A study of Schizosaccharomyces pombe with 29 samples.

How the data were processed

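The series holds 29 two-colour arrays of fission yeast (Schizosaccharomyces pombe). On 21 chromatin immunoprecipitation arrays (ChIP-chip), DNA recovered with a protein or mark was hybridised in the Cy5 channel against input DNA in the Cy3 channel. The groups were the HA-tagged proteins Cdk9 (4 arrays), Rpb3 (4), Mcs6 (3, spelled Msc6 in the labels) and Lsk1 (3), and immunoprecipitations labelled S2A (4) and S5A (3) from a strain with a wild-type polymerase. The labels name the H5 antibody for both of the last groups and do not say what the 2 names stand for, so they are written as labelled. On 8 expression arrays, total RNA of a deletion of lsk1 (4 arrays) or of the rpb1 S2A mutant (4 arrays) was hybridised against wild-type RNA, with the dyes swapped between arrays 1 and 2 and arrays 3 and 4 of each mutant. Per the labels, ChIP-chip cultures of 100 ml grew in rich medium at 32 °C to mid-log phase and were fixed with 3% formaldehyde for 10 min, and DNA was sheared to about 500 bp.

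The ChIP-chip tables give, per the file headers, the foreground and local background intensity of each spot in both channels on a linear scale, with neither channel nor array normalized. The median intensity minus local background, per the file headers, was computed by software that is not named in the sources used here. The expression files give, per the file headers, mean and background intensity per spot, and processed signals that Agilent Feature Extraction 9.5 (per the submitters' processing notes) had background-subtracted and dye-normalized. The deposited log10 ratio of red over green in those files gave no value here, since log2 ratios were taken from the signals themselves. The authors' deposited value tables hold log2 ratios of the same arrays, made by steps not given in the sources used here. Their column medians lay between -0.04 and 0.01 for ChIP-chip and between -0.00 and 0.03 for expression, so they are centred near 0. Set against the scanner values, the expression columns already ran as mutant over wild type (r between 0.941 and 0.995, slope between 1.02 and 1.42 over probes), and the ChIP-chip columns as precipitate over input (r between 0.44 and 0.924). The exact scaling of the ChIP-chip columns stays unknown, and they carry almost no trend with spot intensity (r between -0.043 and 0.146), where the median-centred scanner ratios do (0.452 to 0.847).

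For ChIP-chip, the log2 ratio of background-subtracted medians was centred on each array's median, with no loess, since many probes may truly shift one way. Control spots and spots with a negative quality flag were left out, which removed between 0.604% and 4.6% of the 42707 genomic spots per array, and 13.7%, 19.5% and 26.6% on 3 of the S2A arrays. Probe coordinates were set against the reference ASM294v3 by how well input intensity followed the GC content of the sequence in blocks of 200000 bp. They fitted at no offset (within 80 bp) on chromosomes II and III and on chromosome I up to 3.6 Mb, and were shifted by 6110 to 6150 bp after 3.8 Mb of chromosome I. Genes beyond 3.6 Mb of chromosome I, lsk1 and mei2 among them, were therefore not analysed in ChIP-chip. A gene's value was the mean of the probes centred in it (median 6 probes), and 4093 protein-coding genes had a value on all 21 arrays. One limma fit held all 6 groups (15 residual degrees of freedom). Enrichment was tested with limma's treat against a minimum of 1.5-fold over the array median, and 6 contrasts between groups with limma's moderated test, each with Benjamini-Hochberg adjustment at 0.05. No untagged or mock precipitation was part of the samples used here, so enrichment means signal above the median nuclear probe of the array, and background binding was not subtracted. Occupancy along genes was the median over genes of the last 500 bp minus the first 500 bp, for genes of at least 1500 bp, with exact two-sided permutation tests over arrays and adjustment over the 6 contrasts.

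For expression, mean and background signals were corrected with normexp (offset 50) and loess within each array. Control and outlier spots were left out, dye-swapped arrays were turned to mutant over wild type, and spots, then distinct probes of a gene, were averaged (median 3 probes per gene). Of 15922 probes inside genes, 15444 were well above background in at least 1 channel on enough arrays and were kept. Gene names came from the files, and 5294 of 5365 matched the reference. Arrays 1 and 3, and arrays 2 and 4, were averaged as technical dye swaps of 1 biological sample, since the design text names 2 biological samples with dye-swap replicates per mutant but not which arrays belong together. This gave 2 samples per mutant, fitted together in limma (5258 genes, Benjamini-Hochberg adjustment at 0.05). Every array holds wild-type RNA of 1 strain, and the labels do not say whether it was 1 extract or several, so it was counted as 1 control, and the test of the ratio against 0 leaves out the wild type's own spread. The design text calls the samples and the ChIP-chip arrays biological replicates without saying that they came from separate cultures, so p-values measure the spread between these samples. The normexp offset understates changes of dim genes. From the processed signals without loess, ura4 had a log2 ratio of 8.72 in the lsk1 deletion against 5.23, mug62 4.09 against 2.09 and nmt1 4.17 against 2.04. The median of all genes on single arrays lay between -0.05 and -0.03 after normexp and loess, and between -0.28 and 0.04 from the processed signals without loess, where background correction and loess changed together.

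Gene lists were fixed before the data were examined: CTD kinases, phosphatases and partners, RNA polymerase II subunits, M-cell and P-cell mating genes, sexual differentiation regulators, meiosis-specific genes, nitrogen-starvation response, phosphate acquisition, thiamine-repressed genes, iron uptake, core environmental stress, heat-shock chaperones, glycolysis and fermentation, histones, ribosomal proteins, ribosome biogenesis, cell separation, G1/S genes, flocculation and cell surface, Tf2 retrotransposons, mitochondrially encoded genes and strain markers. List shifts were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, each adjusted over the lists. None of the 8 mitochondrially encoded genes was measured on the expression arrays. Named genes were also fixed by rule before the data were examined: for each mutant, the 10 largest rises and 10 largest falls past the threshold with 1 sign on all 4 arrays, and for their difference the 5 largest each way. For ChIP-chip they were the 5 highest enriched genes per group and the 5 largest differences each way per contrast, with 1 sign over every array pair. Always named were lsk1, rpb1, ura4, ste11, mei2, rpb3, cdk9 and mcs6, and of each list up to 4 members with the smallest p. Genes named outside the rule are said to be so.

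Replicate numbers in the labels were checked for pairing by correlating deviations from group means. Among 15 pairs of ChIP-chip groups, 1 had every correlation over 0.1: Cdk9 and Rpb3, with 4 correlations between 0.117 and 0.242. There the numbers were taken as pairs, from the data alone since the labels state no shared day. With the replicate number as a block, 2114 genes differed between Cdk9 and Rpb3, against 2129 without it. Alternatives covered background correction, loess, filters on dim or flagged probes, the probe summary, scaling between arrays, the authors' value tables, GC content, the replicate block, the pairing of the dye swaps, the fold minimum, the groups in the fit, and each array or sample left out.

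The limma tests of genes were tried on simulated ratios first, for 1 expression comparison and 1 ChIP-chip contrast. In the simulated lsk1 comparison (5258 genes), 100% of genes changed by 1.5-fold or 2-fold were recovered, with 5 unchanged genes called. In the simulated comparison of the S2A group with Rpb3 (4093 genes), 61% at 1.5-fold and 91% at 2-fold were recovered, with 5 unchanged genes called. The number of arrays limits the precision. Tools were R 4.3.3 with data.table, at 1.17.8, and limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.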

Results

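RNA and chromatin occupancy were measured in fission yeast growing in rich medium, in a study of phosphorylation of the carboxy-terminal domain (CTD) of RNA polymerase II on serine 2 and its part in sexual differentiation. The CTD is a tail of short repeats on Rpb1, the largest subunit. The exact repeat core YSPTSP occurs 24 times in the protein encoded by the reference gene, a count that leaves out repeats differing from it. Lsk1 and Cdk9 are kinases of serine 2, Mcs6 is the CTD kinase of the general factor TFIIH, and Rpb3 is a core subunit of the polymerase. RNA was compared with wild type in cells lacking lsk1 and in the rpb1 S2A mutant, named for the replacement of serine 2 of the repeats by alanine (2 biological samples and 4 arrays each). Occupancy was measured by ChIP-chip for tagged Cdk9 (4 arrays), Rpb3 (4), Mcs6 (3) and Lsk1 (3), and for immunoprecipitations labelled S2A (4) and S5A (3). All values are log2 ratios, of mutant over wild-type RNA or of precipitate over input, given as mean ± SD over samples or arrays, and the number of arrays limits their precision. Coordinates are those of the reference ASM294v3.

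The first question was what happens to RNA when the serine 2 kinase Lsk1 is missing. The transcript of ste11 (SPBC32C12.02, chromosome II 3983376 to 3987400), the transcription factor that starts sexual differentiation, fell by 2.15 ± 0.24 on the log2 scale (n = 2, adjusted p = 6.2e-06), the largest fall of any gene passing the rule other than lsk1 itself. With it fell mei2 (SPAC27D7.03c, chromosome I 4510983 to 4515025), the RNA-binding inducer of meiosis, at -1.15 ± 0.26 (adjusted p = 4.87e-05). The mating pheromone gene mfm2 was at -1.51 ± 0.14 and ste4, an adaptor of the pheromone kinase cascade, at -1.43 ± 0.11. Rises were led by ura4 (5.23 ± 0.52), the meiotically upregulated gene mug62 (2.09 ± 0.38) and the thiamine biosynthesis gene nmt1 (2.04). The copper transporter gene ctr4 rose by 1.64 ± 0.75 and the amino acid permease gene dip5 by 1.48 ± 0.09. Falls also included psf3, of the GINS replication complex (-1.48 ± 0.01), the cap methyltransferase gene pcm1 (-1.38 ± 0.03) and the flocculin genes pfl8 (-1.41 ± 0.07) and pfl7 (-1.31 ± 0.18). The remaining genes of the rule rose between 1.45 and 1.98 (SPAC13G6.13, prl11, SPNCRNA.102, SPBC1348.01 and SPAC212.01c) or fell to -1.43 and -1.42 (SPAC11D3.02c and SPBC3B8.08). Probes of prl11, SPBC1348.01 and SPAC212.01c have further exact copies in the genome, so these 3 are uncertain. From the scanner's processed signals without loess, several changes were over 1.5 times as large, with mei2 at -3.73, ste11 at -3.25, ste4 at -3.13, pfl7 at -3.18, pcm1 at -2.47, mfm2 at -2.35, SPAC13G6.13 at 3.22, SPNCRNA.102 at 2.36 and dip5 at 2.50.

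The deleted gene checked the labels. The 3 lsk1 probes (chromosome I 3954812 to 3956080) were at -1.56, -3.11 and -2.98 in the lsk1 deletion, well above background in the mutant channel on 1, 0 and 1 of 4 arrays, against -0.09, 0.57 and 0.74 in the rpb1 S2A mutant. Over the whole gene lsk1 was at -2.55 ± 0.25 (limma, Benjamini-Hochberg adjusted p = 4.01e-06). Per the labels the deletion carries ura4 as its marker, and 3 ura4 probes (chromosome III 115886 to 116385) were at 5.67, 5.48 and 4.56 there. They were at 6.35, 6.10 and 5.34 in the rpb1 S2A mutant, whose label lists no ura4 marker, and the wild-type channel was well above background on all 4 arrays at only 1 of the 3. In total 2361 of 5258 genes passed limma's test in the lsk1 deletion, 956 higher and 1405 lower, of which 33 and 34 changed at least 2-fold. The count rested on both samples, being 1268 without sample 1 and 1114 without sample 2, and was 3605 when the dye swaps were paired the other way round.

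Of all genes tested, 44.9% were called in the lsk1 deletion, the share against which counts within a gene list are read. Among gene groups, the sexual differentiation regulators moved in both directions. Of 25 measured, 2 rose and 6 fell (2 and 6 adjusted over the list alone), no excess over that share. The falls were ste11, ste4, mei2, the MAP kinase kinase gene byr1 (-1.15), the pheromone G protein gene gpa1 (-1.05) and the MAP kinase gene spk1 (-0.64), while byr2, one step above byr1, was at 0.61 (spk1 and byr2 were named after their values were seen). Over the whole list the median was -0.03 and camera gave adjusted p = 0.542. Ribosome biogenesis genes went one way, with 14 of 20 lower and 0 higher (14 adjusted over the list alone). Their median was -0.23 (adjusted p = 0.00297, and adjusted p = 0.508 with an estimated correlation), with nop2 at -0.56 and gar2 at -0.38. CTD kinases and partners had 8 of 18 lower and 0 higher (8 adjusted over the list alone), among them cdk9 at -0.39, its cyclin pch1 at -0.43 and the Lsk1 partners lsc1 (named after its value was seen) and lsg1 at -0.40 and -0.33. Their median was -0.13 (adjusted p = 0.024, and adjusted p = 0.508 with an estimated correlation), and the deleted gene counts among them. From the scanner's processed signals without loess the median was -0.24. Of 141 ribosomal protein genes 18 fell and 0 rose (4 adjusted over the list alone), with a median of -0.08 (adjusted p = 0.0322, and adjusted p = 0.842 with an estimated correlation). From the scanner's processed signals without loess their median was 0.02 and adjusted p = 0.378, so this direction depended on the processing.

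Groups that were higher in the lsk1 deletion included glycolysis and fermentation genes, 9 of 17 higher and 2 lower (11 and 2 adjusted over the list alone). Their median was 0.23 (adjusted p = 0.00235, and adjusted p = 0.508 with an estimated correlation), with the pyruvate decarboxylase gene pdc202 at 0.80 and pgk1 at 0.56, but the enolase gene eno102 at -0.61. Thiamine-repressed genes had 4 of 5 higher (5 adjusted over the list alone), nmt1 and thi9 (0.84) the most, median 0.31 (adjusted p = 0.00235, and adjusted p = 0.508 with an estimated correlation). Core environmental stress genes had 11 of 19 higher and 1 lower (the same 11 and 1 adjusted over the list alone), median 0.20 (adjusted p = 0.00274, and adjusted p = 0.508 with an estimated correlation), such as hsp16 at 0.86 and the glycerol synthesis gene gpd1 at 0.76. Heat-shock chaperones had 7 of 11 higher and 0 lower (7 adjusted over the list alone), median 0.37 (adjusted p = 0.00297, and adjusted p = 0.688 with an estimated correlation). Histone genes had 5 of 10 higher (5 adjusted over the list alone), median 0.19 (adjusted p = 0.0181, and adjusted p = 0.842 with an estimated correlation). Cell separation genes had 7 of 16 higher (7 adjusted over the list alone), median 0.13 (adjusted p = 0.0322, and adjusted p = 0.508 with an estimated correlation), a call that ended with the scanner's processed signals without loess (median 0.15, adjusted p = 0.0924).

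The remaining lists did not pass in the lsk1 deletion. Members higher and lower were 4 and 2 of 10 M-cell mating genes, 2 and 2 of 6 P-cell mating genes, 6 and 3 of 19 meiosis-specific genes and 4 and 7 of 15 nitrogen-starvation genes, with medians of 0.12, 0.09, 0.02 and -0.03 (0.03, 0.04, -0.00 and -0.22 from the processed signals without loess). They were 3 and 1 of 5 phosphate genes, 3 and 2 of 10 iron uptake genes, 1 and 4 of 11 polymerase II subunits, 4 and 4 of 13 G1/S genes, 5 and 4 of 12 flocculation genes, and 2 and 2 of 8 strain markers. Among them the acid phosphatase gene pho1 rose by 1.21 ± 0.22 and the starvation-induced gene isp4 by 1.23. Of 2 Tf2 retrotransposon entries 1 rose, Tf2-11 at 0.39.

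**Figure D1:**
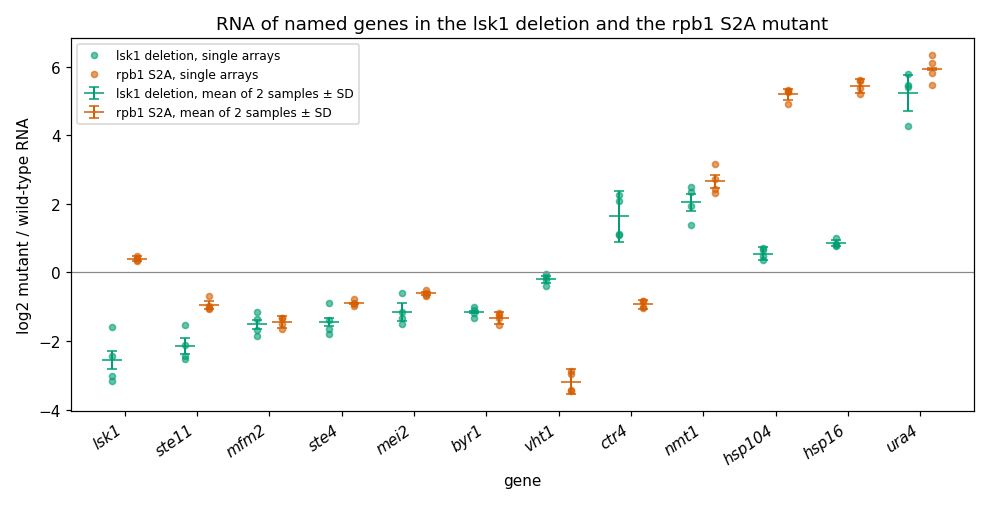
Log2 ratio of mutant over wild-type RNA (vertical axis) for 12 named genes (horizontal axis) in the lsk1 deletion (green) and the rpb1 S2A mutant (orange), with points for the 4 single arrays and bars for the mean of 2 biological samples ± SD. The gene ste11 lies at -2.15 in the deletion and -0.95 in rpb1 S2A, while hsp16 lies at 0.86 and 5.44.

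The rpb1 S2A mutant asked what happens when serine 2 cannot be phosphorylated at all. Here ste11 fell by 0.95 ± 0.11 (adjusted p = 1.97e-05) and mei2 by 0.61 ± 0.04 (adjusted p = 0.000283). The largest rise was that of ura4 (5.93 ± 0.04). The small heat-shock protein gene hsp16 (SPBC3E7.02c, chromosome II 2660139 to 2660992) was at 5.44 ± 0.20 (adjusted p = 3.34e-09), ddr48 at 5.38 ± 0.25, the protein disaggregase gene hsp104 at 5.20 ± 0.16, the Hsp70 gene ssa1 at 4.21 ± 0.06 and the mitochondrial chaperone gene hsp78 at 4.02 ± 0.15. Also above 4 were rtc3 (4.62), SPBC19C7.04c (4.53), slt1 (4.34) and SPCC338.18 (4.17). Among the largest falls, the biotin transporter gene vht1 was at -3.18 ± 0.37, the homocysteine synthesis gene met17 at -2.22 ± 0.14, the carbonic anhydrase gene nce103 at -2.08 ± 0.09 and the zinc transporter gene zrt1 at -1.92 ± 0.14. The remaining falls of the rule lay between -2.55 and -1.91 (SPAC11D3.02c, SPAC8E11.10, SPBC115.03, SPCC965.14c, atl1 and oaa1). From the scanner's processed signals without loess, mei2 was at -1.92, ste11 at -1.59 and SPCC965.14c at -3.37.

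The label check for this mutant came from rpb1 itself. Its probe inside the CTD repeats (chromosome II 1596191 to 1596243, repeats at 1596183 to 1596707) was at -5.96 ± 0.20 in rpb1 S2A and -0.16 in the lsk1 deletion. A probe for the wild-type repeats need not bind a rewritten repeat sequence, so this value checks the label and is no level of the mutant RNA. The other 3 rpb1 probes were at -0.34, -0.42 and -0.61 in rpb1 S2A, where the mutant channel was well above background on 4, 3 and 0 of 4 arrays, so the last value is uncertain. They averaged -0.09 in the deletion. Of the other genes always reported, rpb3 was at -0.60 and mcs6 at -0.63 in rpb1 S2A (adjusted p = 2.43e-05 and 1.99e-05), cdk9 at 0.27 and lsk1 at 0.41. In total 3793 of 5258 genes passed limma's test, 1716 higher and 2077 lower, with 291 and 204 changed at least 2-fold.

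By group, core environmental stress genes stood out in rpb1 S2A, with 17 of 19 higher and 1 lower (17 and 1 adjusted over the list alone). Their median was 1.70 (camera adjusted p = 2.1e-08, and adjusted p = 0.439 with an estimated correlation). Examples were hsp9 at 3.60, the catalase gene ctt1 at 2.59 and the trehalose synthesis gene tps1 at 2.29, while the glutathione transferase gene gst1 was lower at -0.77. All 11 heat-shock chaperone genes measured were higher (11 adjusted over the list alone), from 0.52 to 5.44, with a median of 1.72 (adjusted p = 3.42e-07, and adjusted p = 0.76 with an estimated correlation). The genes hsp16 and hsp104 are in both lists. Cell separation genes had 10 of 16 lower and 1 higher (10 and 1 adjusted over the list alone), median -0.44 (adjusted p = 0.0315, and adjusted p = 0.76 with an estimated correlation). The septum glucanase genes eng1 and agn1 were at -1.55 and -1.49. Ribosomal protein genes had 78 of 141 lower and 13 higher (76 and 13 adjusted over the list alone), median -0.18 (adjusted p = 0.0155, and adjusted p = 0.893 with an estimated correlation), but a median of 0.02 and adjusted p = 0.418 from the scanner's processed signals without loess.

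The other lists did not pass in rpb1 S2A, where 72.1% of all genes tested were called, the share against which the counts of members are read. Sexual differentiation regulators had 7 of 25 higher and 14 lower (7 and 14 adjusted over the list alone), median -0.23 (adjusted p = 0.699), or -0.48 from the scanner's processed signals without loess. Among them byr1 was at -1.32, gpa1 at -0.89 and spk1 at -0.58, but the protein kinase A regulatory gene cgs1 was at 1.73 and the cell fusion gene fus1 at 1.56. Meiosis-specific genes had 11 of 19 higher and 2 lower, median 0.23 (adjusted p = 0.0522), or 0.54 from the processed signals without loess, with dmc1 at 1.56. Members higher and lower were 6 and 3 of 10 M-cell genes, 2 and 2 of 6 P-cell genes, 5 and 8 of 15 nitrogen-starvation genes, 0 and 4 of 5 phosphate genes, 1 and 3 of 5 thiamine genes, and 4 and 5 of 10 iron uptake genes. They were 8 and 6 of 17 glycolysis genes, 2 and 1 of 10 histone genes, 3 and 9 of 20 ribosome biogenesis genes, 3 and 8 of 13 G1/S genes, 1 and 6 of 12 flocculation genes, 3 and 5 of 11 polymerase II subunits, 7 and 8 of 18 CTD kinases and partners, and 3 and 5 of 8 strain markers. The lower polymerase II subunits and strain markers include rpb1, whose mean of -1.83 holds the probe in the CTD repeats and is no level of the mutant RNA. Both Tf2 retrotransposon entries rose, Tf2-11 by 2.34 and Tf2-1 by 2.08, but Tf2 sequences are near-identical copies and 2 entries are too few for a list test.

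The mutants were then compared with each other, to ask whether losing the kinase and losing its target site change the same genes. The fall of ste11 was deeper in the lsk1 deletion by 1.20 (limma, Benjamini-Hochberg adjusted p = 0.000104), and that of mei2 by 0.55 (adjusted p = 0.0049). Differences for mfm2 (-0.06, adjusted p = 0.651) and pcm1 (0.05, adjusted p = 0.584) did not pass. The scanner's processed signals without loess put them further apart, mfm2 at -2.35 in the deletion and -3.21 in rpb1 S2A, and pcm1 at -2.47 and -2.93. Genes highest in the deletion relative to rpb1 S2A were vht1 (by 2.98), ctr4 (2.56), met17 (2.43), pho1 (2.14) and SPCC965.14c (1.98). The genes ctr4 and pho1 moved in opposite directions, ctr4 being at 1.64 and -0.93 and pho1 at 1.21 and -0.93. Genes lowest in the deletion relative to rpb1 S2A were ddr48 (-5.43), SPBC19C7.04c (-5.01), hsp104 (-4.64), hsp16 (-4.58) and SPCC338.18 (-4.42). The core stress list differed by a median of -1.34 (1 higher and 17 lower of 19, adjusted p = 1.68e-08, and adjusted p = 0.434 with an estimated correlation). Heat-shock chaperones differed by -1.72 (0 and 10 of 11, adjusted p = 5.65e-07, and adjusted p = 0.726 with an estimated correlation) and cell separation genes by 0.57 (12 and 1 of 16, adjusted p = 0.00235, and adjusted p = 0.618 with an estimated correlation). These counts were the same adjusted over the list alone. Nitrogen-starvation genes passed only from the processed signals without loess (median 0.84, adjusted p = 0.0458, against 0.50 and adjusted p = 0.073). In total 3218 genes differed between the mutants, 1635 higher and 1583 lower in the deletion.

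Across genes, the 2 mutants' log2 ratios correlated with Pearson's r of 0.408 and Spearman's rho of 0.335 (5258 genes, which are not independent replicates), and 59.8% of genes had the same sign. For the 4 combinations of single samples r lay between 0.311 and 0.473. Unchanged mutants sharing 1 wild-type RNA gave r = 0.502 in 100 simulations with the spread of the samples split evenly between mutant and wild type, and a covariance of 0.00223 against the observed 0.085. That r follows from the even split. The spread between samples also leaves out any deviation that the shared wild-type RNA brings to every sample. The simulated covariance therefore cannot say how much of the observed one comes from the shared control. Of the genes called, 491 were higher in both (312 for independent lists) and 807 lower in both (555 for independent lists). A further 219 were higher in the deletion and lower in rpb1 S2A, and 269 the reverse (377.6 and 458.5 for independent lists). The single wild-type control cannot be split, so part of the excess may come from the shared control. RNA of ura4 was far above wild type in both mutants, so both may also differ from the control in ura4 genotype. Changes that follow from such a difference cannot be told apart here from those of either mutation.

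Chromatin occupancy was compared gene by gene within each of the 6 groups, and several leading genes recurred. The cell wall gene ecm33 (SPAC1705.03c, chromosome I 1569613 to 1571589) was among the 5 highest enriched genes of Cdk9 (4.15 ± 0.40, n = 4), S2A (4.14 ± 0.71, n = 4), S5A (5.60 ± 0.34, n = 3), Lsk1 (3.12 ± 0.12, n = 3) and Rpb3 (3.86 ± 0.12, n = 4). The pyruvate decarboxylase gene pdc101 led Lsk1 (3.34 ± 0.13) and was second for S2A (4.14 ± 0.99), and the alcohol dehydrogenase gene adh1 led S5A (5.62 ± 0.40). The aldolase gene fba1 led Rpb3 (3.99 ± 0.30), ahead of rps3 (3.94 ± 0.27). The leading Mcs6 genes were the histone H3 gene hht2 (3.56 ± 0.19) and the ribosomal protein genes rpl1202 (3.31 ± 0.47), rps2402, rps27 and rpl4102. Cdk9 was led by SPBC19C7.04c (4.89 ± 0.33), which was at 1.15 ± 0.25 for Rpb3, followed by ecm33 and the histone genes hht3, hta1 and hht2. The other leading genes were psu1 and but2 for S2A, pgk1, exg1 and zrt1 for S5A, rps13 for Lsk1 and but2 for Rpb3.

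Of 4093 genes, limma's treat called enriched 878 for Rpb3, 786 for Cdk9, 776 for S5A, 460 for S2A, 281 for Lsk1 and 202 for Mcs6, and 127 were enriched in all 6 groups. The S2A count includes array 4, whose genes spread far less (SD 0.361, against 1.02 to 1.06 on the other S2A arrays), and it was higher without that array. Of the Lsk1 genes 279 were also enriched for Rpb3 (60.28 for independent lists), and of the Mcs6 genes 200 were also enriched for S5A (38.3 for independent lists). The Lsk1 count depended on scaling, being 502 with arrays scaled to a common spread and 1 in the authors' value table. The Rpb3 and Mcs6 counts were 561 and 312 with common spread, and in the authors' table Cdk9, S2A, Mcs6 and Rpb3 had 223, 36, 122 and 232. A 2-fold minimum left 461 for Cdk9, 215 for S2A, 464 for S5A, 117 for Mcs6, 124 for Lsk1 and 443 for Rpb3. Of 114 ribosomal protein genes, enriched ones were 110 for Cdk9, 111 for S5A, 106 for Rpb3, 94 for Mcs6, 91 for Lsk1 and 79 for S2A. Of 7 histone genes between 5 and 7 were enriched in each group, and of 14 glycolysis genes between 8 and 11. Of 7 heat-shock chaperone genes, enriched ones were 7 for S5A, 6 for S2A, 4 for Rpb3, 2 for Cdk9, 1 for Lsk1 and 0 for Mcs6. The tagged genes themselves were at 1.39 ± 0.11 for mcs6 in Mcs6 (higher than 95.9% of genes), 0.93 ± 0.12 for cdk9 in Cdk9 (82.1%) and 0.50 ± 0.06 for rpb3 in Rpb3 (67.2%).

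Each protein or mark was set against Rpb3 to ask where its signal differs from that of the polymerase subunit. Rpb3 was precipitated from a different strain, and so a different culture, than the other groups. A difference from Rpb3 can therefore also come from transcription differing between the strains or cultures. The contrasts with Rpb3 cannot tell this apart from a protein or mark departing from the polymerase. The gene ste11 was far higher for Cdk9 (3.53 ± 0.12) than for Rpb3 (0.95 ± 0.13), a difference of 2.57 that was the 18th highest of 4093 genes. It was low for Lsk1 (-0.49 ± 0.22), a difference from Rpb3 of -1.45 that was the 12th lowest. It was at 1.03 ± 0.88 for S2A, 1.01 ± 0.35 for S5A and -0.00 ± 0.23 for Mcs6. The largest excess of Cdk9 over Rpb3 was at fub2 (6.23), SPCC737.04 (4.96), the uracil-regulated genes urg2 (4.90) and urg1 (4.45), and uck2 (3.81). The phosphodiester transporter gene tgp1 (-2.40), the pyrimidine gene ura1 (-1.81), dpm2 (-1.74), pfk1 (-1.70) and rpb1 (-1.68) had the largest deficit. In total 2129 genes differed between Cdk9 and Rpb3, 1137 higher and 992 lower, or 739 and 1403 with dim-input probes left out. Of 20 sexual differentiation regulators, 9 were higher and 4 lower for Cdk9 than for Rpb3, against 1 and 8 for Lsk1 and 1 and 11 for Mcs6. Group means of Lsk1 and Mcs6 spread less over genes (SD 0.573 and 0.544) than those of Rpb3 (SD 1.01), which can add to such lower calls.

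**Figure D2:**
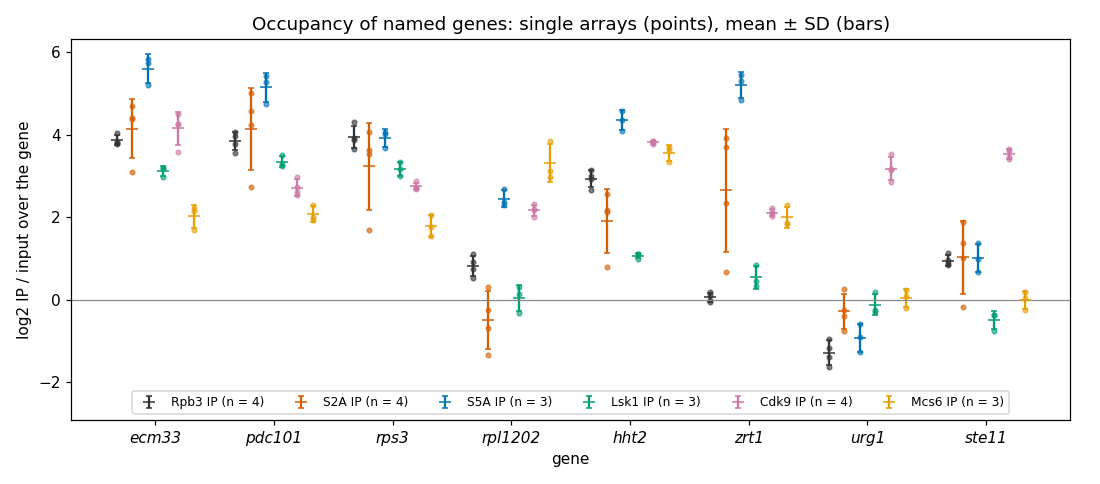
Log2 ratio of precipitate over input (vertical axis) averaged over each of 8 named genes (horizontal axis) for the 6 immunoprecipitations, with points for single arrays and bars for the mean ± SD of 3 or 4 arrays. The gene ste11 lies at 3.53 for Cdk9 and between -0.49 and 1.03 for the other groups, and zrt1 lies at 5.19 for S5A and 0.06 for Rpb3.

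The S5A group exceeded Rpb3 most at zrt1 (5.13, from 5.19 ± 0.31 against 0.06 ± 0.11), followed by SPAPJ695.02 (3.69), SPCC13B11.02c (3.59), SPBPB10D8.01 (3.49) and adh4 (2.85). It was lowest relative to Rpb3 at dpm2, tgp1, mhf2, gep4 and mug130 (-1.68 to -1.52). Histone genes were higher for S5A than Rpb3 at 7 of 7 (median difference 1.69), ribosomal protein genes at 70 of 114 (0.80) and glycolysis genes at 9 of 14 (1.26). In total 1167 genes differed, 775 higher and 392 lower, or 1001 and 280 with arrays scaled to a common spread and 549 and 676 with dim-input probes left out. The total was 722 without S5A array 1 and 2423 when only these groups were fitted. For S2A against Rpb3 the ribosomal protein genes went the other way, 88 of 114 lower and 0 higher with a median difference of -0.90, rps27 (-2.01) and tam9 (-2.66) among the lowest genes. Of the 1436 genes that differed, 314 were higher, led by SPAPJ695.02, SPBPB10D8.01, pfl7, zrt1 and the iron transporter gene str3 (2.25 to 3.07), and 1122 lower, also dpm2, smp2 and new14. These counts were 895 with a common spread, 910 in the authors' value table (312 higher and 598 lower) and 720 when only these groups were fitted. Directly against S5A, S2A was higher at 133 genes, led by map2 (1.42), tlh1, SPBPB8B6.02c, str3 and SPBPB2B2.08, and lower at 1135, led by SPCC13B11.02c (-3.52), SPAC1786.04, rpl4102, rpl1202 and ubi3. Of 114 ribosomal protein genes 107 were lower and 0 higher. The authors' table gave 547 and 1365, and fitting only these groups 431 genes in all.

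Lsk1 exceeded Rpb3 most at tlh1 (3.24), str3 (3.09), SPBPB8B6.02c (2.98), fah1 (2.95) and SPBPB2B2.08 (2.95). At each of these Rpb3 lay below its array median by more than 3, and Lsk1 between -0.55 and 0.17. It was lowest relative to Rpb3 at fhn1 (-1.94), hht2 (-1.87), SPAC23C4.04c (-1.80), rpl4102 (-1.78) and but2 (-1.70), and ribosomal protein genes were lower at 53 of 114 and higher at 1 (median difference -0.66). Group means spread less over genes for Lsk1 (SD 0.573) than for Rpb3 (SD 1.01), which by itself puts highly occupied genes lower for Lsk1. The count for ribosomal protein genes is given without scaling to a common spread, so it cannot show a relative lack of Lsk1 there. The total was 1455 genes, 594 higher and 861 lower. With arrays scaled to a common spread it was 414, 297 higher and 117 lower, with rpl4102 and but2 no longer called, and it was 630 in the authors' table, 963 without Lsk1 array 3 and 2571 when only these groups were fitted. Mcs6 exceeded Rpb3 most at SPCC13B11.02c (4.14), next to adh1, and then at SPBPB2B2.08, SPBC1289.14, fah1 and mug14 (3.05 to 3.21). It was lowest at but2 (-2.60), SPBP23A10.11c (-2.59), the phospholipase gene plb1 (-2.51), scw1 (-2.47) and ura1 (-2.16). Of the 2388 genes that differed, 781 were higher and 1607 lower (474 and 1966 with dim-input probes left out), and 1371 differed in the authors' table, as did 1349 for Cdk9. Across genes the group means correlated with Rpb3 at r = 0.872 for S2A, 0.871 for S5A, 0.88 for Lsk1, 0.748 for Cdk9 and 0.644 for Mcs6, over genes that are not independent replicates.

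Along genes, the proteins lay in different places. On 163 genes of at least 1500 bp with the highest Rpb3 signal, Cdk9 and Mcs6 were higher in the first 500 bp, with 3' minus 5' values of -0.96 ± 0.13 (n = 4) and -0.82 ± 0.03 (n = 3). Rpb3 itself was higher in the last 500 bp (1.38 ± 0.11, n = 4), as was S2A (1.35 ± 0.61, n = 4) and, less so, Lsk1 (0.62 ± 0.11, n = 3). S5A was nearly even (-0.13 ± 0.05, n = 3). Averaged in bins of 100 bp, Mcs6 peaked at the annotated 5' end (2.62), Cdk9 was highest 200 bp inside it (2.58) and Rpb3 lay between 2.30 and 2.50 from 700 bp inside the annotated 3' end to 200 bp past it. On 38 ribosomal protein genes, each divided into 3 equal parts and the last taken minus the first, Lsk1 was at 1.21 ± 0.08 and Rpb3 at 1.12 ± 0.22, and Cdk9 and Mcs6 were again below 0 (-0.45 and -0.85). The differences from Rpb3 were -2.34 for Cdk9, -2.20 for Mcs6, -1.52 for S5A and -0.76 for Lsk1, each with an exact two-sided permutation p = 0.0286, the smallest possible (35 regroupings of 3 against 4 arrays, 70 of 4 against 4), and Benjamini-Hochberg adjusted p = 0.0429 over 6 contrasts. That test ignores the pairing of Cdk9 and Rpb3 arrays by number. Flipping signs within the 4 pairs, an exact test chosen after seeing the data, cannot go below p = 0.125 and gave that value for Cdk9 (adjusted p = 0.15). The adjustment then took S5A, Lsk1 and Mcs6 to adjusted p = 0.0571, so 0 of the 6 contrasts passed. Without the pairing, S2A showed no difference past the threshold from Rpb3 (-0.03, adjusted p = 1) or from S5A (1.49, exact permutation p = 0.0571, adjusted p = 0.0686). S2A array 4 stood apart at 0.45, and without it S2A exceeded Rpb3 by 0.28 (adjusted p = 0.0343). Lsk1 lost its difference on the ribosomal protein genes (0.09). In the authors' value table the differences from Rpb3, itself at 0.58 there, were -1.0005 for Cdk9, -1.22 for Mcs6, -0.56 for S5A and -0.26 for Lsk1.

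**Figure D3:**
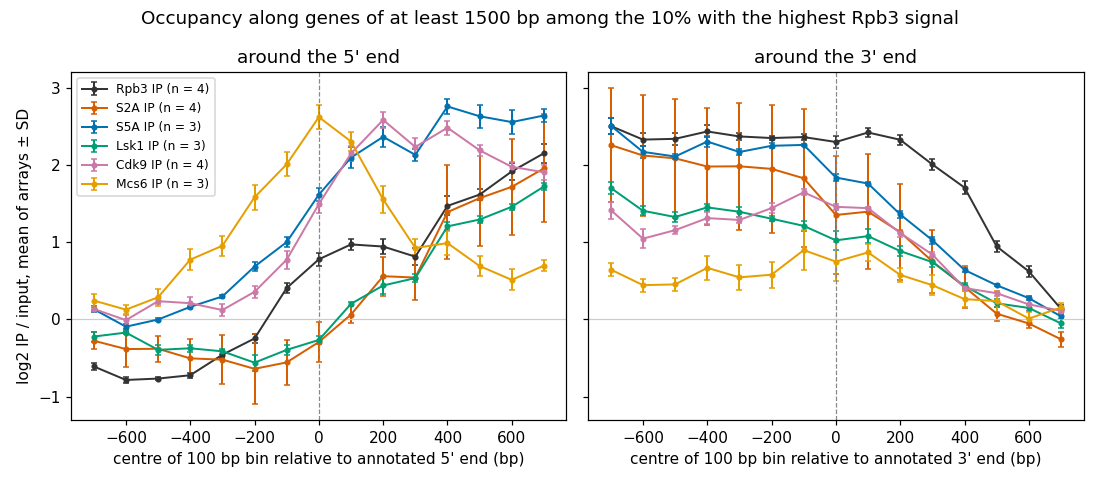
Mean log2 ratio of precipitate over input ± SD over arrays (vertical axis) in bins of 100 bp around the annotated 5' and 3' ends (horizontal axes, bp) of genes of at least 1500 bp among the 10% with the highest Rpb3 signal, for 6 immunoprecipitations. Mcs6 peaks at 2.62 at the 5' end, while Rpb3 is at 2.42 in the bin 100 bp past the 3' end.

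**Figure D4:**
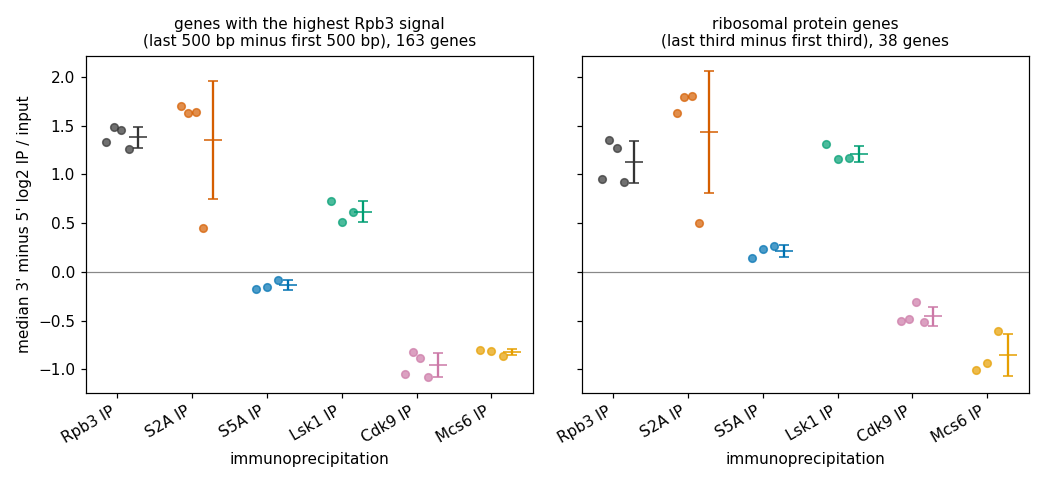
Median 3' minus 5' log2 ratio of precipitate over input (vertical axis) per array (points) with the group mean ± SD (bars) for 6 immunoprecipitations (horizontal axis), on 163 genes with the highest Rpb3 signal (left) and 38 ribosomal protein genes (right). Rpb3 averages 1.38 and Cdk9 -0.96 on the left, and S2A array 4 lies at 0.45 below the other S2A arrays.

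The last question was whether genes changed in the mutants are those with more or less Lsk1 or polymerase on them. The 1803 genes changed in the lsk1 deletion that had ChIP-chip values did not stand out for Lsk1, their median lying -0.02 from that of other genes (percentile 5.21 among 10000 random lists of that size). They lay slightly lower for the S2A group (-0.08 ± 0.04, n = 4, percentile 0.05) and for Rpb3 (-0.07 ± 0.01, n = 4, percentile 1.48). By direction, genes lower in the deletion were lower for the S2A group (-0.12, percentile 0), as they were for S5A (-0.07, percentile 0.88), and those higher were not past the threshold in any group (0.03 at percentile 66.03 for S2A). For the 100 genes with the smallest p the differences were -0.32 for S2A, -0.31 for Rpb3, -0.26 for Cdk9, -0.29 for S5A, -0.12 for Mcs6 and -0.10 for Lsk1, the last at percentile 2.82 and the others past the threshold of 2.5. The 1245 genes higher in rpb1 S2A were lower than other genes in every group, by -0.19 for Rpb3 and -0.10 for Lsk1, below every random list. The 1638 genes lower in rpb1 S2A were higher, by 0.16 for Rpb3 and 0.09 for Lsk1, at or above percentile 99.96. Taking only the 100 genes with the smallest p, 9 values by direction over both mutants lost their call. Those lower in rpb1 S2A no longer stood apart in any group, and those higher in it did not stand apart in every group.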

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

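Chosen only after the result was seen were the tests of wild-type RNA from cells lacking ura4, of a low level in the shared wild-type RNA, and of transcripts extending past annotated 3' ends.

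Among the ChIP-chip arrays, S2A array 4 lay far from the other S2A arrays on 5 measures. Its genes spread less (SD 0.361 over genes, against 1.02 to 1.06). Its 3' minus 5' value was 0.45 on the genes with the highest Rpb3 signal, 0.11 on all genes of at least 1500 bp and 0.50 on ribosomal protein genes, and but2 was at 2.11. Elsewhere, Cdk9 array 3 lay apart on ribosomal protein genes (-0.31) and Rpb3 array 2 at ecm33 (4.04). Of 42 groups of values tested this way, chance flags about 1 in 20 groups.

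The lsk1 deletion and rpb1 S2A differed in 3218 genes by limma's test of the difference, with 219 genes higher in the deletion and lower in rpb1 S2A and 269 the reverse. By list, core environmental stress differed by -1.34, heat-shock chaperones by -1.72 and cell separation genes by 0.57.

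Probes outside the gene comparisons held RNA signal above wild type. At least 2-fold above wild type in rpb1 S2A were 425 of 2978 probes antisense to a gene, 1211 of 7257 between genes and 587 of 4901 further probes inside a gene on the same strand. In the lsk1 deletion these were 139, 509 and 238. At least 2-fold below wild type, in the same order, were 16, 139 and 207 probes in rpb1 S2A and 6, 51 and 34 in the deletion. As shares of probes, those above wild type were 14.27%, 16.69% and 11.98% in rpb1 S2A and 4.67%, 7.01% and 4.86% in the deletion. Of the genes compared, 5.53% and 0.628% were at least 2-fold higher. These gene shares count means over the probes of a gene, while the others count single probes. The units differ, so the shares cannot show an excess over genes.

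RNA of ura4, the marker gene of the pyrimidine pathway, was above wild type in both mutants. The lowest of the 3 ura4 probes in either mutant was at 4.56, while 17 neighbouring genes within 20 kb had medians of -0.16 and -0.00. That is consistent with wild-type RNA from cells lacking ura4, though the wild-type label lists no ura4 allele. Against a deleted gene, the wild-type channel was well above background on all 4 arrays at 1 of the 3 probes (chromosome III 115886 to 115943), 5.67 and 6.35 below the mutants, so a low level stays open. A rise of the pyrimidine pathway in the mutants is argued against by ura1, ura2, ura3 and ura5, whose medians were -0.28 in the deletion and -0.72 in rpb1 S2A.

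Stress and heat-shock genes were above wild type in rpb1 S2A. A low level in the shared wild-type RNA is argued against by the lsk1 deletion, measured against the same wild type, since the core stress list was 1.504 higher in rpb1 S2A, but only if both were set against the same RNA extract, which the labels do not say. The 2 rpb1 S2A samples differed by 0.0226 over both lists (1.55 and 1.57). That argues against a single stressed culture only if the samples came from separate cultures and the assumed pairing of arrays holds. The sources state neither. Acute stress of both cultures at growth or harvest cannot be told apart from the mutation by ribosome biogenesis genes, which it would lower and whose median was -0.14 with 9 lower and 3 higher of 20, and 78 of 141 ribosomal protein genes were lower. A lasting response to the changed repeats stays open too, and no test here decides it.

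RNA signal within 200 bp past annotated 3' ends was above wild type in the lsk1 deletion. Over 741 probes of 733 genes, the median probe exceeded its own gene body by 0.30 (0.21 to 0.35 on single arrays), and 412 probes were higher and 40 lower than wild type, against 317 and 189 in rpb1 S2A. This is consistent with transcripts extending past the annotated end, though where they end was not mapped. A shift of all dim probes is argued against by probes of matched intensity, which these probes exceeded by 0.22 (lowest array 0.11). Farther out the excess over the gene body in the deletion was 0.18 up to 500 bp, 0.09 up to 1000 bp and still 0.09 beyond. In rpb1 S2A it was 0.13 within 200 bp and 0.24 in the farthest bin. There the probes within 200 bp differed from those of matched intensity by -0.096 (-0.1356 to -0.0595 on single arrays). The 0.13 in rpb1 S2A is therefore no excess over dim probes.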

How the results depend on the processing

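Chosen after seeing the data were the correction for GC content, keeping low-quality spots, the replicate block with crossed numbers, and the signs flipped within pairs, and the rest was planned.

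Of the main results under the alternatives, 271 values stayed, 50 moved, 33 were weaker, 5 stronger and 2 reversed. A count stayed when it changed by no more than the fold limit given below for the replicate block, whatever its spread. Tested values stayed when they kept their side of the threshold, and the correlation of the mutants when it lay within its spread. For single named genes and gene directions 2956 stayed, 30 were weaker, 13 stronger and 3 reversed. Where no construction explains a change, the cause was not tested. A block by slide was not run, since the labels give no slide or scan day.

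Genes changed in the lsk1 deletion were 3605 with the dye swaps paired the other way, and 1114 to 2988 with a sample left out, where the lone sample is assumed to vary like the others. With an estimated correlation, camera called 0 gene lists in the lsk1 deletion, 0 in rpb1 S2A, 0 for their difference and 0 in all.

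With arrays scaled to a common spread, enriched genes were 312 for Mcs6, 502 for Lsk1 and 561 for Rpb3, and 895 genes differed for S2A and 414 for Lsk1 against Rpb3. In the authors' value table, enriched genes were 223 for Cdk9, 36 for S2A, 122 for Mcs6, 1 for Lsk1 and 232 for Rpb3. Against Rpb3, 910 differed there for S2A, 630 for Lsk1, 1349 for Cdk9 and 1371 for Mcs6, and 1912 between S2A and S5A. A 2-fold minimum, stricter by construction, left 461 for Cdk9, 215 for S2A, 464 for S5A, 117 for Mcs6, 124 for Lsk1 and 443 for Rpb3. With only the groups compared in the fit, the spread came from fewer arrays, and 720 genes differed for S2A, 2423 for S5A and 2571 for Lsk1 against Rpb3, and 431 between S2A and S5A. Leaving out arrays gave 963 to 1182 genes for Lsk1 and 722 to 960 for S5A against Rpb3, and 663 enriched S2A genes without S2A array 4.

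Along genes, the last of 3 equal parts minus the first on ribosomal protein genes put S5A at -0.91, Cdk9 at -1.58, Mcs6 at -1.98 and Lsk1 at 0.087 (reversed) from Rpb3. None passed (0 contrasts), because 3 smallest possible p-values among 6 contrasts adjust to 0.0571. In the authors' table Lsk1 was at -0.26, no longer past the threshold, and S2A minus S5A at 0.43, now past it. Leaving out arrays gave -2.38 to -2.30 for Cdk9, -0.82 to -0.71 for Lsk1, -2.25 to -2.17 for Mcs6, -1.56 to -1.48 for S5A and -0.14 to 0.28 for S2A against Rpb3, with 0 to 5 contrasts called, since fewer arrays allow no smaller p.

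For occupancy of the 100 changed genes with the smallest p, differences in the lsk1 deletion were -0.26 for Cdk9, -0.29 for S5A and -0.12 for Mcs6, and in rpb1 S2A -0.23 for Rpb3, all now past the threshold, making 6 calls. Genes higher in the deletion turned to -0.49 for Cdk9, -0.31 for S2A and -0.47 for S5A.

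With the replicate number as a block, 2967 genes differed between the mutants, and 3631 with crossed numbers. Deviations from the group means correlated at -0.234 there. Against Rpb3 the block gave 1427 genes for S2A, 1149 for S5A, 1304 for Lsk1, 2114 for Cdk9 and 2338 for Mcs6, and 1229 for S2A against S5A. Same-numbered ChIP-chip arrays correlated at -0.279 to 0.242 over 45 pairs, so apart from Cdk9 and Rpb3 they share only a number, and the block moved no count of genes by over 1.5 times. Along genes, flipping signs within the Cdk9 and Rpb3 pairs left the differences from Rpb3 at -2.34 for Cdk9, -1.52 for S5A, -0.76 for Lsk1 and -2.20 for Mcs6, but 0 contrasts passed, since 4 pairs allow no p under 0.125 and the other contrasts are adjusted with it. No paired analysis was possible for enrichment because each array already holds its own input.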

Other observations

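The split counts were planned, and the values in the other paragraphs were chosen after the data were seen.

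Mitochondrial DNA on the ChIP-chip arrays (66 spots) lay far below the median nuclear probe for 4 groups, at -5.80 ± 0.29 for Rpb3, -4.46 ± 0.48 for Cdk9, -3.35 ± 0.39 for S5A and -3.23 ± 0.10 for Mcs6. It was less low for Lsk1 (-1.54 ± 0.51) and S2A (-0.89 ± 0.89).

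Input DNA over ura4 (chromosome III 115344 to 116940) was read at 7 spots picked for a negative quality flag on most arrays. Low values in most groups were thus partly built into the choice. On the log2 scale the input differed from the 69 flanking spots by -6.22 for Mcs6, -5.04 for S5A, -2.56 for Cdk9, -2.35 for S2A and -2.02 for Rpb3. For Lsk1, whose label names a ura4 marker, the input differed by 0.07. The labels list the allele ura4-D18 for all 6.

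For S2A, array 4 correlated with the others of its group at 0.693 to 0.727 over genes, and the other 3 with each other at up to 0.895.

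For 5 contrasts of ChIP-chip groups, 1 of 35 splits of the same arrays gave as many genes, the real one. That share argues against chance at 0.05, but it does not exclude it, since 1 of 35 is the smallest share possible there. The share was not adjusted over the contrasts. For S2A against Rpb3 the real count was 1436 and the highest other 148. For S5A against Rpb3 these were 1167 and 119, and for Lsk1 1455 and 24. For Cdk9 against Rpb3, where the numbers pair the arrays, the 8 splits that part every pair are too few for a share under 0.05, with 2129 genes in the real one and 0 in the highest other. For Mcs6 against Rpb3 they were 2388 and 1356, the latter from a split that moved 1 Rpb3 array to the Mcs6 side. For S2A against S5A they were 1268 and 1250, the latter from a split that put S2A array 4 with S5A, which points to a structure within the S2A arrays.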
